A study of Mus musculus with 7 samples.

How the data were processed

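Bulk RNA-seq of sorted Bmi1-marked mouse intestinal crypt cells was examined in 7 libraries from 3 diets. Per the labels' protocols, RNA was amplified with the SMART-Seq v4 kit and libraries were made with Nextera XT and sequenced as paired ends, a preparation that does not mark strand. The deposited counts are whole numbers per Ensembl gene, with 37310 genes in the table. Per the submitters' processing notes, the tools named were STAR 2.4.2a, HTSeq 0.6.1 and edgeR, without a version, and the build was mm9, and the notes give neither roles nor order. The labels do not state the annotation, the strand setting or any filter. The deposited TPM values, named as such by the file and each column summing to 1000000, come with the same notes, and the gene lengths used are not stated. TPM served only as an alternative.

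Diet, sex, replicate number and i5 index were taken from the labels. The TPM table has 1 column headed as NWD2 replicate 3. No sample has that title, while the sample titled NWD1 replicate 3 has no TPM column. That column was not used, and the TPM alternative holds 6 samples. The conflict makes the diet of NWD1 replicate 3 less certain, and results without that library are given. The annotation at hand is of another build than mm9, so no coordinates are printed. Gene symbols are those deposited with the TPM values. A table of current Ensembl IDs, with which 32620 IDs matched, served only for symbols not found among them.

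The main test was the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM scaling, filterByExpr on diet and robust fitting. All 7 samples entered one fit with diet as the only term, which left 4 residual degrees of freedom. Of the genes, 14626 were tested, and the biological coefficient of variation was 0.363. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. An exact permutation test of a single gene could not go below p = 0.333 with 2 against 2 samples or 0.1 with 3 against 2, so none was used. CPM are scaled by TMM. SEs are those of the fitted log2 fold changes, except where they are said to be over genes.

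The lists of cell types and pathways were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. There were 33 lists, of which 1, of sex-linked genes, served only to check labels and was not tested. The 32 tested are the 15 shown in the plot of list changes and the 17 named as called in none. Of the 801 symbols of all 33 lists, 799 matched the table, 4 of them by a newer symbol. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over all 96 tests. A list's mean is over its measured members. The genes named per comparison were to be those passing the adjusted p with the largest changes. As fewer than 10 passed, they are the 10 of smallest p with an average log2 CPM of at least 1 and a symbol that is not a clone or predicted-gene name. A fixed set of marker genes was always named.

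The alternatives were DESeq2 size factors or library size as scaling, no filter or 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma voom, limma on log2(TPM + 1) with fold changes on that scale, replicate number, sex or i5 index as a term, only the 2 diets compared, an adjusted p under 0.1, a log2 fold change of at least 1, each library left out in turn, and for lists an estimated correlation and fry. Thinning all libraries to the shallowest was added after the data were seen. Where a diet is left with 1 library, that library is assumed to vary like the others. As NWD1 replicate 2 was the only female, a sex term in effect leaves that library out. Only NWD1 carried both i5 indices, the second in replicate 3 alone. An i5 term thus in effect leaves NWD1 replicate 3 out of NWD1 against AIN76A. In the NWD2 comparisons the i5 effect rests on that library alone.

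The tests were also run on simulated counts with the means, dispersions and library sizes of the main fit, over 14626 genes. Simulated genes varied independently, so the simulations hold none of the correlation between real genes. For NWD1 against AIN76A, 7.46%, 73.1% and 97.0% of genes set to a log2 fold change of 1, 2 and 3 were recovered, with 4 false calls. For NWD2 against AIN76A the shares were 1.49%, 61.2% and 95.5%, with 9 false calls. For NWD2 against NWD1 they were 10.5%, 70.2% and 98.5%, with 3 false calls. Few changes of 1 on the log2 scale were thus recovered. These shares need not carry to the data, where Fxyd6, at -2.36 with NWD2 against AIN76A, had an edgeR adjusted p of 0.831. In 1 simulation that lowered the enteroendocrine list by 1 in NWD2, camera called that list in both NWD2 comparisons. It also called 1, 2 and 1 of the lists that were not shifted, in the order of the comparisons, namely MHC class II in both NWD2 comparisons and the stromal, endothelial and glial list in both AIN76A comparisons. Shared controls were simulated 20 times. Genes with near-identical copies, such as alpha-defensins, and genes that overlap on opposite strands cannot be told apart by such counts and are uncertain. Transcript length and GC content came from the longest transcript in the GENCODE vM21 annotation, which is of another build, and covered 96.6% of the tested genes. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.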

Results

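The series compared diets in mouse intestinal cells marked by Bmi1, a Polycomb gene whose reporter has been used to label reserve stem cells of the crypt. Mice carrying an inducible Bmi1 Cre and a red fluorescent reporter received their diet from weaning to 3 months of age. Crypt cells that were strongly red, positive for the epithelial protein Epcam and negative for the leukocyte protein CD45 were sorted, and their RNA was sequenced in bulk. AIN76A is a purified control diet. NWD1 is a purified Western-style diet with more fat and less calcium, vitamin D3 and methyl donors, and NWD2 is NWD1 with calcium and vitamin D3 raised again. There were 7 libraries, 2 for AIN76A, 3 for NWD1 and 2 for NWD2. The labels do not say whether each came from its own animal, so p-values of single genes measure the spread between these samples only. Camera p-values at the preset correlation treat the genes of a list as nearly independent, and do not measure the spread between libraries. The estimated correlation was 0.97 for ribosomal proteins with NWD1 against AIN76A. With NWD2 against AIN76A it was 0.66 for tuft cell and 0.16 for enteroendocrine markers. Total counts were 58419160 and 39657707 in AIN76A, 44260145, 65822352 and 14034315 in NWD1, and 71331627 and 77959407 in NWD2, in the order of their replicate numbers. All samples were labelled male except NWD1 replicate 2. Xist, the RNA of the inactive X chromosome, had 3325 counts there against at most 13 elsewhere, and the Y-linked Ddx3y had 2 counts there and at least 455 elsewhere.

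Libraries of the same diet were about as similar as libraries of different diets. Across genes, which are not independent replicates, the median Pearson r of log2 CPM was 0.965 within diets and 0.963 between diets. The first principal component held 27.3% of the variance and set NWD2 replicate 2, at 84.2, apart from the other libraries, which lay between -48.2 and 1.44. That library also had the lowest Epcam, 225 CPM against 510 to 1337 elsewhere. For the genes after which such cells are named, the values of single libraries overlapped between the diets. Bmi1 had 3.07 ± 0.93 CPM (SD, n = 2) in AIN76A, 3.76 ± 1.57 (SD, n = 3) in NWD1 and 3.09 ± 0.76 (SD, n = 2) in NWD2. Hopx, another reserve stem cell gene, had 98.9 ± 14.2, 81.7 ± 19.7 and 90.9 ± 9.43 CPM. Lgr5, the marker of cycling crypt base stem cells, had 7.29 ± 6.06, 7.09 ± 3.27 and 9.27 ± 4.37 CPM. Olfm4 and Ascl2, of the same cells, had log2 fold changes from -0.41 to 0.56 over the 3 comparisons.

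**Figure D1:**
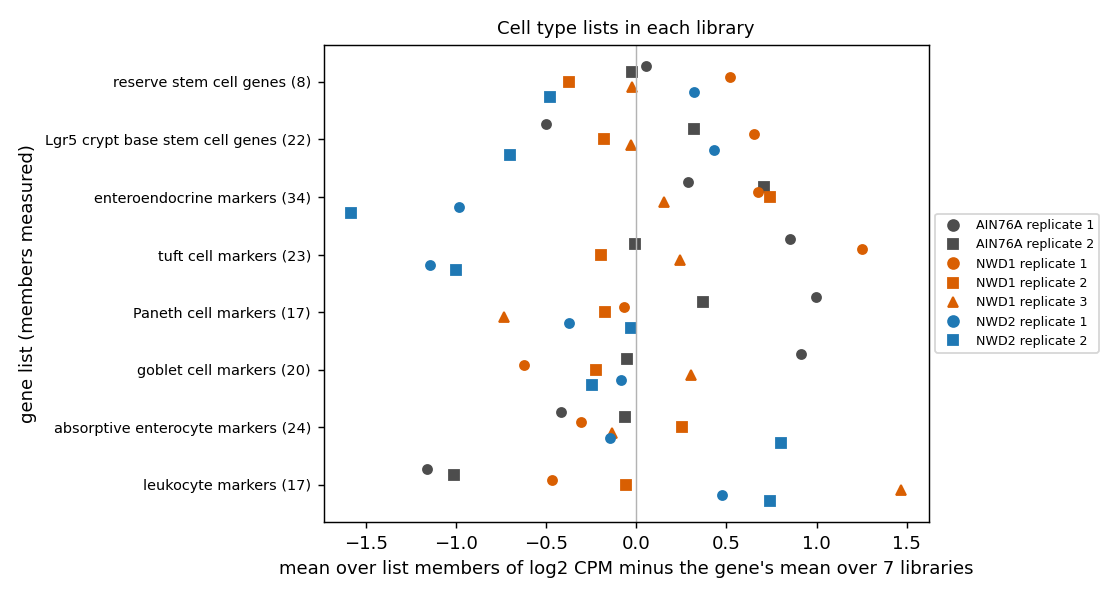
Mean over the members of each cell type list of log2 CPM minus the gene's mean over the 7 libraries, on the horizontal axis, with a point per library coloured by diet and shaped by replicate number. The NWD2 libraries lie at -0.98 and -1.58 for enteroendocrine markers and at -1.14 and -1.0 for tuft cell markers, below the other 5 libraries in both lists.

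The comparison of NWD1 with AIN76A asks what the Western-style diet changed. Paneth and goblet cell markers were lower with NWD1. All 17 measured markers of Paneth cells, the antimicrobial cells at the crypt base, had negative log2 fold changes, with a mean of -0.76. The list fell by limma camera (adjusted p = 2.94e-09; adjusted p = 0.608 with an estimated correlation). Lyz1, encoding lysozyme, had 11980 ± 2233 CPM (SD, n = 2) in AIN76A and 7044 ± 1840 (SD, n = 3) in NWD1, and Defa17, an alpha-defensin, had 735 ± 312 and 295.0 ± 46.1 CPM. Alpha-defensins have near-identical copies, so counts of single members are uncertain. Goblet cell markers, genes of the mucus-secreting cells, were lower in 18 of 20 members, with a mean of -0.56, and the list fell (camera adjusted p = 8.76e-09; adjusted p = 0.769 with an estimated correlation). AIN76A replicate 1 had the highest score of the 7 libraries in both lists. Without it the Paneth mean was -0.37 with the call kept, while the goblet mean was 0.04 and that call was lost. Without AIN76A replicate 2 the means were -1.15 and -0.94, and without NWD1 replicate 3, or with an i5 index term, the goblet mean was -0.93.

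Ribosomal protein, oxidative phosphorylation and cholesterol synthesis genes were also lower with NWD1. All 52 cytosolic ribosomal protein genes had negative values, with a mean of -0.70, and the list fell (camera adjusted p = 2.61e-18; adjusted p = 0.769 with an estimated correlation). The same held for 59 of 61 oxidative phosphorylation genes, with a mean of -0.47 (camera adjusted p = 6.79e-14; adjusted p = 0.769 with an estimated correlation). Without AIN76A replicate 1 these means were -0.24 and -0.07, and the oxidative phosphorylation call was lost. The ribosomal mean was -1.20 without NWD1 replicate 1, and the oxidative phosphorylation mean was -0.77 without AIN76A replicate 2. Cholesterol synthesis genes were lower in 21 of 24 members, with a mean of -0.34 (camera adjusted p = 2.86e-06; adjusted p = 0.769 with an estimated correlation).

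The tricarboxylic acid cycle, glycolysis, cell cycle and MHC class II lists fell with NWD1 too, with means of -0.22, -0.21, -0.26 and -0.58 and camera adjusted p of 0.00784, 0.0246, 0.00105 and 0.0115. With an estimated correlation the adjusted p was 0.769 for each but the cell cycle, for which it was 0.873. Each of these calls was lost when 1 library was left out. Without AIN76A replicate 1 the means of the tricarboxylic acid cycle, glycolysis and MHC class II lists were -0.13, -0.03 and -0.04 and their calls were lost. The cell cycle call was lost without AIN76A replicate 2 (mean -0.05) and without NWD1 replicate 3 or with an i5 index term (-0.09 each), while its mean was -0.40 without AIN76A replicate 1 and -0.39 without NWD1 replicate 1. The glycolysis call was also lost without NWD1 replicate 1 (-0.17), and its mean was -0.36 without AIN76A replicate 2. The MHC class II call was also lost without NWD1 replicate 1 (-0.15) or NWD1 replicate 2 (-0.29). A sex term, which in effect leaves out NWD1 replicate 2, ended that call too (-0.29). Its mean was -0.94 without AIN76A replicate 2, and -1.84 without NWD1 replicate 3 or with an i5 index term.

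Leukocyte markers were higher with NWD1 in all 17 measured members, with a mean of 1.97 (camera adjusted p = 1.27e-08; adjusted p = 0.646 with an estimated correlation), although the sort removed cells with CD45. Their levels were low. The lysosomal membrane gene Laptm5 had 0.02 and 0.12 CPM in AIN76A and 0.35, 0.94 and 2.19 CPM in NWD1, and NWD1 replicate 3 had the highest list score. With an i5 index term the list mean was 1.21 and the call was kept. Ptprc, which encodes CD45, had 3.26 ± 0.96 CPM (SD, n = 2) in AIN76A and 4.12 ± 2.29 (SD, n = 3) in NWD1. Genes of proximal small intestine identity were higher in 12 of 14 members, with a mean of 0.65 (camera adjusted p = 0.0249; adjusted p = 0.769 with an estimated correlation). That call was lost without AIN76A replicate 1, AIN76A replicate 2 or NWD1 replicate 2, with means of 0.64, 0.71 and 0.52, and with a sex term (0.52).

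The list of vitamin D receptor targets and calcium transport genes was not called between NWD1 and AIN76A (mean 0.83, median 0.10, camera adjusted p = 0.0767). Of its 11 members 6 were higher and 5 lower, and 2 passed adjusted over the list alone against 0 over all genes tested. Slc30a10, a manganese exporter, had 16.5 and 18.7 CPM in AIN76A and 32.5, 86.3 and 53.8 CPM in NWD1. The calcium channel gene Trpv6 reached 10.9 CPM in NWD1 replicate 2 and at most 0.46 CPM elsewhere. Trpv6 and the list members Laptm5, Trpm5, Neurog3, Lct, Cyp51, Defa20, Defa21, Defa22 and Defa26 were picked after their values were seen.

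Single genes did not pass between NWD1 and AIN76A. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14626 genes, with 500 at an unadjusted p under 0.05 where chance gives 731. DESeq2 called 1 and limma voom 0. The 10 named genes of smallest p had edgeR adjusted p = 0.878. The chromatin remodeller gene Chd3 (log2 fold change 1.77, SE 0.45), the choline kinase gene Chka (1.76, SE 0.46), Slc30a10 (1.71, SE 0.45), Zfpm1, Ltb4r1, Slc16a9 and Tmem189 were higher, with values from 1.52 to 1.84. The chemokine gene Ccl20 (-1.75, SE 0.48), Defa17 (-1.32, SE 0.38) and Ramp1 (-1.12, SE 0.33) were lower.

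The comparison of NWD2 with AIN76A asks what differed from the control diet once calcium and vitamin D3 were raised. Markers of hormone-producing enteroendocrine cells were lower with NWD2 in all 34 measured members, with a mean log2 fold change of -1.72. The list fell by camera (adjusted p = 4.74e-49; adjusted p = 0.184 with an estimated correlation), and 26 members passed adjusted over the list alone against 0 over all genes tested. Chga, a protein of hormone granules, had 456 ± 109 CPM (SD, n = 2) in AIN76A and 139 ± 47.4 (SD, n = 2) in NWD2. Gip, the incretin hormone of K cells, had 551 ± 87.9 and 104 ± 26.6 CPM. Tuft cell markers, genes of chemosensory cells, were lower in all 23 members, with a mean of -1.57. That list fell as well (camera adjusted p = 2.02e-23; adjusted p = 0.608 with an estimated correlation), and 14 members passed adjusted over the list alone against 0 over all genes tested. Dclk1, a tuft cell kinase, had 38.1 ± 6.11 and 15.3 ± 5.46 CPM. Both calls were kept without any single library, with means between -2.30 and -1.43 and between -1.81 and -1.06. They were also kept with an i5 index term, with means of -1.09 and -1.07, but that term rests on NWD1 replicate 3 alone.

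**Figure D2:**
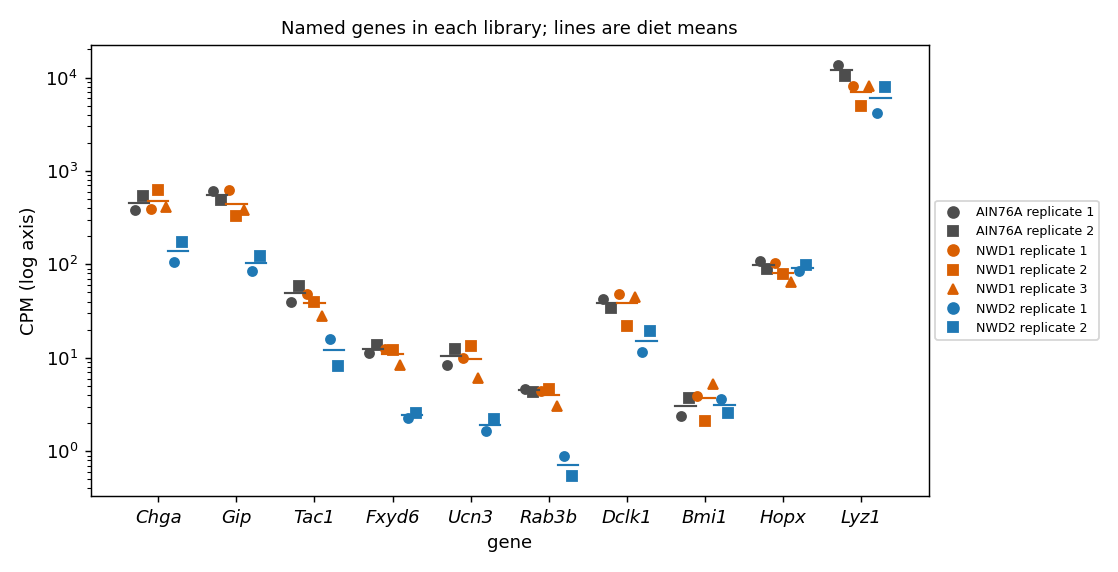
CPM on a log axis for 10 named genes, with a point per library coloured by diet and shaped by replicate number, and a line at each diet's mean. For Chga the NWD2 libraries lie at 105 and 172 CPM and the other libraries between 379 and 626, while for Bmi1 and Hopx the diets overlap.

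Other secretory and absorptive markers also differed between NWD2 and AIN76A. Paneth cell markers were lower in all 17 members, with a mean of -0.88 (camera adjusted p = 1.04e-08; adjusted p = 0.608 with an estimated correlation). The mean was -0.49 without AIN76A replicate 1, and -0.24 with an i5 index term, where the call was lost. That term rests on NWD1 replicate 3, where the members Defa20, Defa21, Defa22 and Defa26 had only 35, 8, 140 and 98 counts. With it Defa21 had a log2 fold change of 6.86, so the Paneth mean with that term leans on these genes. Goblet cell markers were lower in 16 of 20, with a mean of -0.58 (camera adjusted p = 6.21e-08; adjusted p = 0.769 with an estimated correlation). Without AIN76A replicate 1 the goblet mean was 0.03 and the call was lost, without AIN76A replicate 2 it was -0.95, and with an i5 index term -1.28. Absorptive enterocyte markers were higher in 22 of 24, with a mean of 0.64 (camera adjusted p = 3.15e-07; adjusted p = 0.769 with an estimated correlation). Proximal small intestine genes were higher in 11 of 14, with a mean of 0.80 (camera adjusted p = 0.0036; adjusted p = 0.769 with an estimated correlation). Both rested on NWD2 replicate 2, where the lactase gene Lct had 3383 CPM against 452 to 1160 elsewhere. Without that library the means were 0.05 and -0.07 and both calls were lost, and the proximal call was also lost with an i5 index term (0.67).

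Leukocyte markers were higher with NWD2 than with AIN76A in 16 of 17 members, with a mean of 1.92 (camera adjusted p = 4.05e-11; adjusted p = 0.608 with an estimated correlation). The call was lost with an i5 index term (0.40). Levels of the list were low, as in the comparison of NWD1 with AIN76A. The 1 member that was lower was Ptprc, which encodes CD45 (log2 fold change -1.30, SE 0.62). It had 3.26 ± 0.96 CPM (SD, n = 2) in AIN76A and 1.32 ± 0.22 (SD, n = 2) in NWD2. Interferon response genes, which cells switch on against viruses, were higher in 32 of 36 members, with a mean of 0.64 (camera adjusted p = 6.9e-09; adjusted p = 0.769 with an estimated correlation). The mean was 0.39 without NWD2 replicate 1 and turned to -0.04 with an i5 index term. MHC class II genes, which present antigen, were lower in all 7 members, with a mean of -1.65 (camera adjusted p = 8.32e-06; adjusted p = 0.769 with an estimated correlation). That call was lost without NWD2 replicate 1 (-1.40), and the mean was -1.10 without AIN76A replicate 1 and -4.01 with an i5 index term. Camera also called this list for NWD2 in simulated counts in which it was not changed.

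Cholesterol synthesis genes were higher with NWD2 than with AIN76A in 21 of 24 members, with a mean of 0.28 (camera adjusted p = 0.00226; adjusted p = 0.769 with an estimated correlation), a call lost without AIN76A replicate 2 (0.26). With an i5 index term the mean was 0.58. The cell cycle list fell, with a mean of -0.43 (camera adjusted p = 2.86e-06; adjusted p = 0.769 with an estimated correlation). Ribosomal protein genes were lower in all 52 members, with a mean of -0.50 (camera adjusted p = 3.15e-07; adjusted p = 0.853 with an estimated correlation). Without NWD2 replicate 2 these last means were -0.04 and -0.09 and both calls were lost. The cell cycle call was also lost without AIN76A replicate 2 (-0.21), and the ribosomal call without AIN76A replicate 1 (-0.03). With an i5 index term the means were 0.17 and 0.11 and neither was called. Without NWD2 replicate 1 they were -1.06 and -1.14, and without AIN76A replicate 2 the ribosomal mean was -0.84.

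Of single genes, edgeR called 0 of 14626 between NWD2 and AIN76A, with 560 at an unadjusted p under 0.05 where chance gives 731. DESeq2 called 52, of which 50 were lower, 11 were enteroendocrine markers and 1 was a tuft cell marker, and limma voom called 0. The 10 genes of smallest p by edgeR were all lower, with adjusted p = 0.831, and did not pass. They were the ion transport regulator gene Fxyd6 (log2 fold change -2.36, SE 0.35), Gip (-2.40, SE 0.40), the vesicle protein gene Rab3b (-2.64, SE 0.45), the retinol carrier gene Rbp4 (-2.66, SE 0.50), the peptide hormone gene Ucn3 (-2.44, SE 0.46), Rab3c, Resp18, Tac1, Anxa6 and Rgs4. The last 5 had values between -2.38 and -1.74. The i5 index divides NWD2 from AIN76A completely, and only NWD1 carried both indices, the second of them in replicate 3 alone.

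The comparison of NWD2 with NWD1 asks what the added calcium and vitamin D3 changed. Enteroendocrine markers were lower with NWD2 in 33 of 34 members, with a mean of -1.81. The list fell (camera adjusted p = 3.26e-37; adjusted p = 0.184 with an estimated correlation), and 28 members passed adjusted over the list alone against 0 over all genes tested. The exception in sign was Neurog3, the transcription factor gene of enteroendocrine progenitors, at 0.38 (SE 0.91). Chga had 478 ± 129 CPM (SD, n = 3) in NWD1 against 139 ± 47.4 (SD, n = 2) in NWD2, and Tac1, encoding substance P, had 38.7 ± 10.2 against 12.1 ± 5.34. Tuft cell markers were lower in all 23 members, with a mean of -1.68. That list fell (camera adjusted p = 4.32e-18; adjusted p = 0.703 with an estimated correlation), and 20 members passed adjusted over the list alone against 0 over all genes tested. Trpm5, the cation channel gene of taste signalling, had 56.4, 25.4 and 44.3 CPM in NWD1 and 12.9 and 15.4 CPM in NWD2. Both calls were kept without any single library, with means between -2.39 and -1.66 and between -1.94 and -1.24, and with an i5 index term, with means of -1.32 and -1.28. That term rests on NWD1 replicate 3 alone, which shares its i5 index with the NWD2 libraries. This library had scores of 0.15 for enteroendocrine and 0.24 for tuft cell markers, above both NWD2 libraries. The TPM table has a column headed as NWD2 replicate 3 and none for this library, and if it were an NWD2 library, 1 of 3 NWD2 libraries would lack these low scores.

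Cholesterol synthesis genes were higher with NWD2 than with NWD1 in 22 of 24 members, with a mean of 0.62 (camera adjusted p = 3.08e-12; adjusted p = 0.608 with an estimated correlation). Of them 14 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone or over all genes tested. Cyp51, encoding a sterol demethylase, had 53.6, 84.8 and 57.6 CPM in NWD1 and 121 and 190 CPM in NWD2 (log2 fold change 1.25, SE 0.30). Interferon response genes were higher in 35 of 36, with a mean of 0.65 (camera adjusted p = 7.04e-10; adjusted p = 0.769 with an estimated correlation). The mean was 0.40 without NWD1 replicate 1 and also without NWD2 replicate 1, and 0.28 with an i5 index term, where the call was lost. Oxidative phosphorylation genes were higher in 58 of 61, with a mean of 0.26 (camera adjusted p = 2.95e-05; adjusted p = 0.873 with an estimated correlation). That mean was 0.44 without NWD1 replicate 1, 0.16 without NWD1 replicate 3 and 0.52 with an i5 index term.

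The tricarboxylic acid cycle, glycolysis and absorptive enterocyte lists rose with NWD2 against NWD1, with means of 0.35, 0.34 and 0.42 and camera adjusted p of 0.000778, 0.0036 and 0.00207 (adjusted p = 0.769 with an estimated correlation for each). Without NWD2 replicate 2 these means were 0.05, 0.05 and -0.17 and the calls were lost. The enterocyte call was also lost without NWD1 replicate 1 (0.30). Without NWD2 replicate 1 the enterocyte mean was 0.74 and the glycolysis mean 0.51. Ribosomal protein genes were higher in 51 of 52, with a mean of 0.20 (camera adjusted p = 0.0224; adjusted p = 0.927 with an estimated correlation). Scaled by library size alone, the oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, enterocyte and ribosomal means were 0.02, 0.08, 0.07, 0.13 and 0.01. That scaling shifted the median of all genes by -0.24, and the calls, which are relative to other genes, were kept. The ribosomal call was lost without NWD1 replicate 2 (-0.02), NWD1 replicate 3 (0.03) or NWD2 replicate 1 (-0.42), and with a sex term (-0.02). The mean was 0.70 without NWD1 replicate 1, 0.62 without NWD2 replicate 2 and 0.63 with an i5 index term.

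**Figure D3:**
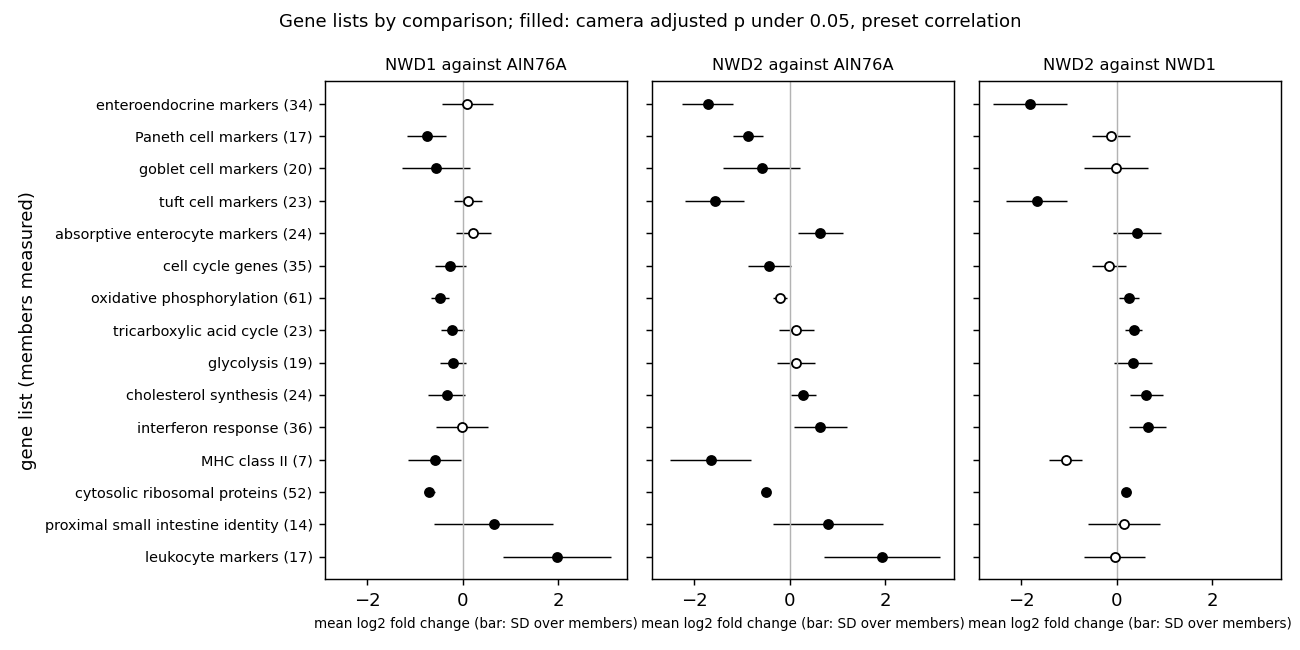
Mean log2 fold change over the measured members of the 15 lists called in at least 1 comparison, on the horizontal axis, with bars for the SD over members, a panel per comparison and filled points for lists that passed camera with the preset correlation. Enteroendocrine markers lie at 0.10, -1.72 and -1.81 in the 3 panels and tuft cell markers at 0.11, -1.57 and -1.68.

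Of single genes, edgeR called 0 of 14626 between NWD2 and NWD1, with 1154 at an unadjusted p under 0.05, of which 987 were lower with NWD2, where chance gives 731. DESeq2 called 180, of which 176 were lower, 18 were enteroendocrine and 7 tuft cell markers, and limma voom called 0. The 10 named genes of smallest p by edgeR were all lower, with adjusted p = 0.472, and did not pass. They were Fxyd6 (log2 fold change -2.17, SE 0.34), the adhesion protein gene Amigo2 (-3.71, SE 0.63), the trophoblast glycoprotein gene Tpbg (-3.52, SE 0.60), Rab3b (-2.48, SE 0.43), Gip (-2.09, SE 0.38), Ucn3, Nebl, Fkbp9, Bambi and Rcn1. The last 5 had values between -2.36 and -1.56.

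Other genes followed in every comparison did not pass in any. Muc2, the main mucin of goblet cells, had 571 ± 194, 418 ± 195 and 350.0 ± 8.9 CPM in AIN76A, NWD1 and NWD2 (SD; n = 2, 3 and 2). In the same order the alkaline phosphatase gene Alpi had 2689 ± 839.5, 4295 ± 412 and 3309 ± 680.1 CPM, the proliferation gene Mki67 had 31.3 ± 3.93, 29.7 ± 3.83 and 19.1 ± 9.62 CPM, and the vitamin D receptor gene Vdr had 485 ± 124, 520.5 ± 82.4 and 611 ± 153 CPM. Enteroendocrine and tuft cell markers were not called between NWD1 and AIN76A (camera adjusted p = 0.956 and 0.932), nor were interferon response (mean -0.01) and enterocyte genes (0.22). Oxidative phosphorylation (mean -0.21, camera adjusted p = 0.0575), tricarboxylic acid cycle (0.14) and glycolysis (0.13) were not called with NWD2 against AIN76A. Between NWD2 and NWD1 the Paneth (-0.12), goblet (-0.02), cell cycle (-0.17), MHC class II (-1.07), proximal small intestine (0.15) and leukocyte (-0.05) lists were not called.

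The 17 lists called in no comparison were reserve stem cell genes, Lgr5 crypt base stem cell genes, fatty acid oxidation and PPAR targets, fatty acid and triglyceride synthesis, vitamin D receptor targets and calcium transport, folate and methyl donor metabolism, Wnt targets, Notch pathway, NF-kB and cytokines, p53 targets, DNA repair, unfolded protein response, immediate early and dissociation stress, antioxidant and detoxification, ileal and colonic identity, stromal, endothelial and glial markers, and histones. Their smallest camera adjusted p was 0.0568, for folate and methyl donor metabolism with NWD1 against AIN76A (mean -0.14). In the stromal, endothelial and glial list, 2 members were higher and 1 lower with NWD2 than with AIN76A adjusted over the list alone, and 1 higher and 1 lower against NWD1, with 0 over all genes tested. In every list not given such a count, 0 members passed adjusted over the list alone. Median, mean and test direction differed in sign in 11 of the 96 list tests, of which 0 were called.

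The changes of NWD1 and NWD2 against AIN76A share the same control libraries. Across genes their log2 fold changes had a Pearson r of 0.46, against 0.56 (SD 0.01) in 20 simulations of unchanged groups set against shared controls. The covariance was 0.232, against 0.227 (SD 0.009) in the simulations, a difference of 0.00556. At an unadjusted p under 0.05, 43 genes were higher in both and 36 lower in both, where the simulations gave 116 and 59.4 and independent lists would give 4.34 and 3.48. The 2 control libraries cannot be split into parts of 2. The excess over independent lists was no larger than shared controls alone gave in the simulations.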

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

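Thinning to the shallowest library was chosen only after the data were seen, and all other alternatives were planned. Against 0 genes by edgeR in each comparison, testing without a filter called 85 genes for NWD1 against AIN76A, 190 for NWD2 against AIN76A and 384 for NWD2 against NWD1. DESeq2 called 1 (AI662270), 52 and 180. Limma on log2 TPM called 1, 0 and 1, mt-Co3 both times. The TPM alternative lacks NWD1 replicate 3, which had 0 mt-Co3 counts against 5049 and 6584 in NWD1 replicates 1 and 2. For NWD2 against AIN76A, the fit with only 2 diets called 6 (Itgb2, Ctse, Ada, Rbp4, Aldh4a1, Cck). An i5 index term called 1 for NWD2 against AIN76A (Defa21) and 2 for NWD2 against NWD1 (Defa20 and Defa21). Leaving out each library gave 0 to 1 genes for NWD2 against NWD1, the 1 being Gm10925 without NWD2 replicate 2, and 0 in the other comparisons. The other scalings, filters and thresholds, a sex term, limma voom and thinning called 0 in each. Beyond the values given, the cause of these counts was not tested.

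The labels do not say what replicate numbers mark. Deviations of same-numbered libraries correlated between -0.000223 and 0.261, over 0.1 in 3 of 6 pairs, and AIN76A replicate 2 correlated best with NWD1 replicate 3 (0.166). The numbers were not treated as pairs. With a replicate block the gene counts were 0, 1 (Tmprss15) and 0, and the list counts 14, 13 and 11 against 11, 12 and 9. The block ended the calls of cell cycle genes for NWD1 against AIN76A (-0.10) and ribosomal proteins for NWD2 against NWD1 (0.07). For NWD1 against AIN76A it moved the means of leukocyte markers to 1.02, MHC class II to -1.91 and goblet cell markers to -0.84, with the calls kept.

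With an estimated correlation or fry's directional p, 0 lists were called in each comparison. Fry's p for change in either direction, which does not compare with other genes, passed in both NWD2 comparisons for enteroendocrine and stromal, endothelial and glial markers (adjusted p at most 0.0163). For NWD2 against NWD1 an i5 index term called 14 lists, and leaving out each library called 10 to 16, with 14 without NWD2 replicate 1 and 16 without NWD2 replicate 2. For NWD2 against AIN76A, the i5 term reversed the means of cell cycle genes (0.1745) and interferon response (-0.04411), and leaving out libraries moved proximal small intestine identity between -0.07088 (without NWD2 replicate 2) and 1.087. For NWD2 against NWD1, it moved absorptive enterocyte markers between -0.1659 (without NWD2 replicate 2) and 0.735, and cytosolic ribosomal proteins between -0.4191 (without NWD2 replicate 1) and 0.6964. The cause was not tested. A sex term ended the calls of MHC class II (-0.29) and proximal small intestine identity (0.52) for NWD1 against AIN76A and of ribosomal proteins (-0.02) for NWD2 against NWD1. As it in effect leaves out NWD1 replicate 2, it is no separate adjustment. In all, 470 of 576 values of called lists kept direction and call, 5 changed test direction, and the rest were no longer called. The mean changed sign in 10, these 5 and goblet cell markers without AIN76A replicate 1 (0.04 for NWD1 and 0.03 for NWD2 against AIN76A), ribosomal proteins for NWD2 against AIN76A with the i5 term (0.11), and ribosomal proteins for NWD2 against NWD1 with a sex term and without NWD1 replicate 2 (-0.02 each). Enteroendocrine and tuft cell markers in both NWD2 comparisons, and cholesterol synthesis in both NWD1 comparisons, lost their calls only with an estimated correlation or fry.

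Of 1425 values of named genes, 1373 stayed on the same side of the threshold, 52 passed only in an alternative and 82 of those not called changed sign. Scaling by library size alone shifted the median of all genes by 0.107, -0.128 and -0.239 in the 3 comparisons, DESeq2 size factors by at most 0.011. With library size alone all list calls were kept, but the means of the cell cycle, tricarboxylic acid cycle and glycolysis lists for NWD1 against AIN76A were -0.16, -0.11 and -0.10, and that of cholesterol synthesis was 0.14 for NWD2 against AIN76A and 0.38 against NWD1, where that of interferon response was 0.43. The correlation of the NWD1 and NWD2 changes was 0.351 among genes with an average log2 CPM of at least 4 and 0.358 as a Spearman correlation, against 0.456. The cause was not tested.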

Other observations

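The tests of dilution by enterocytes, of the i5 index and of fewer Paneth cells were chosen only after the result was seen, and so were the genes named here.

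Enteroendocrine and tuft cell markers were lower in the NWD2 libraries. Both NWD2 libraries lay below the other 5 in 2 of 32 lists, these 2, and above them in 2, cholesterol synthesis and interferon response, where chance gives 1.52 each way. Dilution by absorptive enterocytes would lower the markers of all other crypt cell types alike. Against NWD1 the 57 enteroendocrine and tuft cell markers averaged -1.76 and the 59 Paneth, goblet and Lgr5 stem cell markers -0.10, a difference of 1.654 (SE 0.122). Against AIN76A the means were -1.66 and -0.42, a difference of 1.24 (SE 0.116). These SEs are over marker genes, which vary together, and do not measure the spread between libraries. For these libraries both differences argue against dilution as the whole cause, though not as a test set in advance. The 2 lists were picked for being low in NWD2, which can widen such a gap. Against AIN76A the Paneth (-0.88) and goblet (-0.58) lists fell and enterocyte markers rose (0.64), so dilution may account for part of the fall there. None of these calls held with an estimated correlation. The goblet mean was 0.03 without AIN76A replicate 1, and the enterocyte mean was 0.05 without NWD2 replicate 2. Removing the trend of fold change on transcript length and GC content left 91.97% of the mean (-1.62, SE 0.09 over genes). This argues against that bias as the whole cause. The i5 index cannot be told apart from diet, since 1 library outside NWD2 carries the second index. Relative to the libraries with the first index, that library lay at -0.36 and the NWD2 libraries at -1.75. The TPM table names an NWD2 replicate 3 in place of that library, and whether its diet label is right stays open. Fewer enteroendocrine and tuft cells among the sorted cells, a shift in the sort gate, or lower expression per cell may each underlie the pattern, and none of these was tested.

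Defa20, Defa21, Defa22 and Defa26, alpha-defensin genes of Paneth cells, had 35, 8, 140 and 98 counts in NWD1 replicate 3 and at least 1760 elsewhere. Fewer Paneth cells would lower the other Paneth cell markers too, but these 13 averaged 0.36 there against -4.78 for the 4 genes. The difference was 5.137 (SE 1.03 over genes, in that library alone). Lower depth would remove the gap on thinning, but the lowest of the other libraries thinned to the same depth kept 3233 counts of the 4 genes against 281, a ratio of 11.51. Both tests argue against these explanations. A variant of the defensin gene cluster in that sample may also be a cause. It was not tested, since genotypes were not used here, and no biological explanation from the design was tested. The 4 genes have near-identical copies, so their single counts are uncertain.

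Dbp, Tef, Per3 and Ciart, output and clock genes of the circadian cycle, were highest in NWD1 replicate 1. Dbp had 16.1 CPM there against 0.115 to 2.18 elsewhere, and Tef 37.2 against 4.70 to 12.4. Arntl, Npas2 and Clock, which peak in the opposite phase, were lowest there, with a mean log2 CPM difference of -1.088 from the other libraries, as collection at another time of day would need. Nr1d1 was not highest there (103 CPM in AIN76A replicate 2 was above it). The 4 genes had a mean difference of 3.033, and the 95% range of 10000 level-matched sets was -0.54 to 0.86. As the 4 genes were picked for being highest there, their place outside that range is no test of them. The range itself argues against a general rise of that size among genes of that level in that library. A smaller general shift, or one of transcription factor genes, stays open. Collection at another time of day is a candidate explanation, and the labels give no time.

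Some genes stood apart in single libraries of a diet. The mitochondrial gene mt-Co3 had 5049 and 6584 counts in NWD1 replicates 1 and 2 and at most 11 elsewhere, while mt-Co1 had 44172 to 348492 in all libraries. The antimicrobial lectin gene Reg3b had 10366 CPM in NWD1 replicate 3 and 23404 CPM in NWD2 replicate 1, against 881 to 1657 elsewhere, and Reg3g had 6213 and 15027 CPM against 749 to 2105. The heat shock gene Hspa1b had 64.3 CPM in NWD2 replicate 1 against 1.72 to 9.69 elsewhere. The calcium-binding gene S100g had 104 and 39.1 CPM in AIN76A, 224, 384 and 137 in NWD1, and 29.5 and 111 in NWD2.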
